A study of Mus musculus with 20 samples.

How the data were processed

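RNA was sequenced from sorted CD4 T cells of spleen and lymph nodes of C57BL/6 mice aged 8 to 12 weeks. Naive cells were taken outside the gate for a Foxp3-GFP reporter, as CD44-low cells. Those within the 15% with the lowest or the 15% with the highest surface CD5 are called CD5lo and CD5hi here. They were lysed at once (fresh) or after 22 hours of culture with interleukin 7 at 10 ng per mL (rested). Regulatory T cells (Treg) were taken by Foxp3-GFP and lysed at once. Per the labels, the sort left out cells with surface markers of B cells, NK cells, dendritic cells, macrophages (F4/80 and CD11b) and granulocytes, and cells with the activation marker CD69. Polyadenylated RNA was made into libraries without a stated strand protocol, and reads of 50 bases were taken from both ends. Each of the 5 groups has 4 libraries, which the labels call biological replicates and describe as pooled from both sexes.

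The authors deposited a table of read counts for 22068 gene symbols in the 20 libraries. The submitters' processing notes name TopHat2 2.0.11, featureCounts 1.4.5 of Subread, edgeR and the mm9 build, without their order. The annotation and the strand setting are not given in the sources used here. No coordinates are therefore printed, and a gene and an antisense partner cannot be separated. Of the counts between 1 and 10, 62.3 to 66.2% per library were even, so most fragments appear to have been counted once per mate, and limits set by counting error are optimistic. The counts held no mitochondrially encoded gene symbols. A second deposited table holds a normalized signal for 10147 of these genes. In it the authors' values were proportional to the counts within each library, with a factor per library near that of CPM. It was used only to check that both tables hold the same libraries. All columns of both tables were mapped to samples by title.

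Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with trimmed-mean-of-M-values (TMM) scaling and the default expression filter on the groups. The model had 1 factor with 5 levels, which leaves 15 residual degrees of freedom, and the filter left 13309 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Levels are CPM (counts relative to the TMM-scaled library total), given as mean ± SD with n = 4. Changes are log2 fold changes, given with their SE. The SE is the size of the change over the square root of its quasi-likelihood F, which is unreliable for changes near 0. Comparisons were CD5hi against CD5lo when fresh and when rested, rested against fresh in each CD5 group, and Treg against each fresh group. The interaction is the CD5hi-to-CD5lo difference after resting minus that before. On simulated counts with 200 changed genes, 79.1% of 2-fold changes were recovered for CD5hi against CD5lo when fresh (13032 genes run), 91.0% when rested (13038 genes) and 76.1% for the interaction (13049 genes). Of 1.5-fold changes, 74.6%, 67.2% and 61.2% were recovered in the same order. For rested against fresh, 80.6% of 2-fold changes were recovered in CD5lo cells (13041 genes) and 82.1% in CD5hi cells (13049 genes). For Treg, 83.6% were recovered against CD5lo (13041 genes) and 89.6% against CD5hi (13066 genes). False calls made up 2.98 to 6.25% of the calls. Apart from the changed genes, all groups were simulated with the same mean and spread per gene and without pairs of libraries. Each share rests on 67 changed genes, so differences between the comparisons do not describe fresh, rested or Treg libraries.

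The design, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except those named below as added. A total of 28 gene lists were tested with camera of limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01, and adjusted over 196 tests. Each was tested again with a correlation estimated from the libraries. Named genes are the sort markers and the 8 largest rises and 8 largest falls per comparison without overlap between libraries and with at least 10 CPM in the higher group (5 and 5 for the interaction). Up to 4 members of each list by size of change with at least 1 CPM, and 6 TCR-induced genes in each comparison of naive cells, were named too. Predicted genes and antigen receptor segments were left out of the largest changes, and some genes were left unnamed for length. Some further genes that the rule takes are not reported here. A list's count adjusted over the list alone uses only its own members and gives the number higher and then the number lower. The p-values of the main fit measure a spread estimated jointly over all 20 libraries, not that of the compared groups alone. Rested libraries varied more than fresh ones, so for unpaired libraries this shared spread is too wide for fresh and too narrow for rested comparisons. The main fit leaves aside the pairing of CD5lo with CD5hi libraries described below. Spread that pairs share drops out of CD5hi against CD5lo, where a block within states called 1961 rested genes against 1092. For that comparison the shared spread is thus not shown to be too narrow.

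Within each group every pair of libraries differed by 4.92 to 88.3 times the sampling noise, by a chi-square per degree of freedom over genes, so none was counted as a duplicate. The replicate numbers of the labels paired CD5lo with CD5hi libraries within a state. Deviations from the group means correlated at 0.160 to 0.299 across genes for the 4 fresh pairs and at 0.189 to 0.517 for the 4 rested pairs. Rested CD5lo replicate 4 correlated higher with another number, at 0.218. Numbers did not pair fresh with rested libraries, where no correlation of the same number reached 0.1. Replicate 3 of Treg correlated at 0.376 with that of rested CD5lo and at 0.357 with that of rested CD5hi cells. Other same-number pairs of rested with Treg libraries stood at -0.0137 to 0.172. A block of replicate numbers common to all groups was set before the data were examined. A block set separately in fresh and in rested libraries, a sex covariate, male libraries only, female rested and Treg libraries with all fresh ones, and subsets of rested replicates were added after the data were seen, as was the use of other filters on low counts for single named genes. Male libraries only leaves 1 library in each rested group and in Treg, and that library is assumed to vary like the fresh libraries. Other alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 4 libraries, a fit on only the groups compared, and leaving out each library in turn. A group with 0 counts of a gene is given with the level that 3 counts over its 4 libraries would have.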

Results

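Transcripts of CD4 T cells were counted in 20 libraries of mouse spleen and lymph node cells, in 5 groups of 4. Total counts ran from 51060992 to 58269055 per library in fresh CD5lo cells, 43770193 to 59065224 in fresh CD5hi cells, 43429158 to 64477566 in rested CD5lo cells, 38211406 to 50654225 in rested CD5hi cells and 43509126 to 54555773 in Treg. CD5 is a surface inhibitor of T cell receptor (TCR) signalling whose level on naive cells follows the strength of their contact with self-peptide. The design, per the series' text, compares naive cells of low and high CD5 at homeostasis, 22 hours after removal of that contact, and against Treg. The first principal component took 56.2% of the variance and parted Treg from naive cells. The second took 22.8% and parted fresh from rested naive cells, and the third, with 4.70%, parted CD5lo from CD5hi.

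The sorts were traced by their own markers. Cd5 averaged 148 ± 9.83 CPM in fresh CD5lo cells, 982 ± 61.3 in fresh CD5hi cells, 94.5 ± 6.49 and 461 ± 19.3 in the rested groups, and 606 ± 17.1 in Treg. Foxp3, the transcription factor of Treg, averaged 22.4 ± 1.02, 24.1 ± 1.39, 23.3 ± 0.494 and 28.6 ± 2.77 CPM in the naive groups in that order and 722 ± 38 in Treg. Libraries with Y-linked reads were unevenly spread over the groups. All 8 fresh libraries had 366 to 405 CPM of 4 Y-linked genes and at most 0.721 CPM of Xist. In the rested and Treg groups, replicate 3 alone carried Y-linked reads. Their replicates 1, 2 and 4 held 755 to 1736 CPM of Xist with at most 0.149 CPM of the Y-linked genes. No library thus held both in quantity, whereas the labels describe pools of both sexes. Sex therefore differed between fresh and rested groups and between fresh naive cells and Treg, but not between CD5lo and CD5hi cells of the same state.

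**Figure D1:**
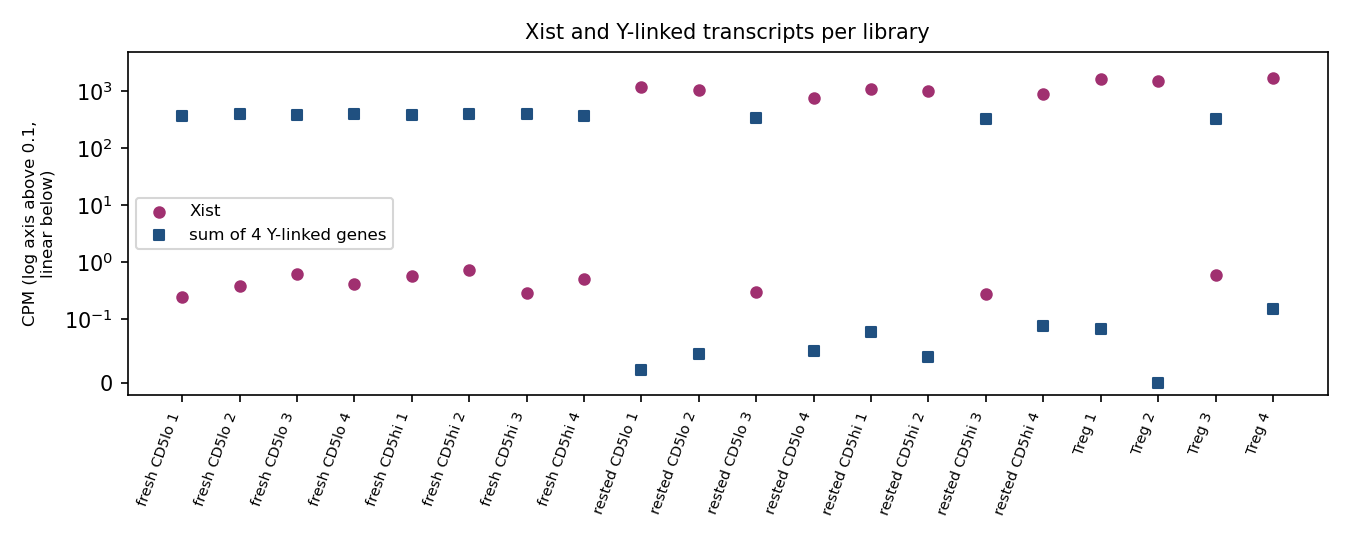
Xist (circles) and the sum of 4 Y-linked genes (squares) in CPM for each of the 20 libraries, on an axis that is logarithmic above 0.1 and linear below. The 8 fresh libraries and replicate 3 of the rested and Treg groups carry Y-linked reads.

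Fresh CD5hi cells carried more transcripts of TCR-induced genes, of inhibitors of TCR signalling and of genes known from Treg than fresh CD5lo cells. Cd5 itself was higher by a log2 fold change of 2.73 ± 0.06 (edgeR, Benjamini-Hochberg adjusted p = 6.2e-18). The largest rise among the named genes was in Itih5, from 3.05 ± 0.953 to 61.2 ± 6.85 CPM, a log2 fold change of 4.32 ± 0.14. Chn2 (3.40 ± 0.14), Phactr2 (3.30 ± 0.16), Tnfrsf9 (2.82 ± 0.12), Folr4 (2.65 ± 0.07), Nt5e (2.58 ± 0.13) and Lysmd2 (2.46 ± 0.12) followed. Folr4, also called Izumo1r, marks Treg and anergic CD4 cells, Nt5e encodes the ectonucleotidase CD73, and Tnfrsf9 encodes 4-1BB. Dntt, the terminal transferase of thymocytes, fell from 28.7 ± 2.86 to 1.98 ± 0.354 CPM (-3.86 ± 0.14). Gprin3 (-2.94 ± 0.15), Ly6c1 (-2.04 ± 0.25), Cd8b1 (-2.01 ± 0.10) and Car2 (-1.98 ± 0.21) were lower as well. In all, 1524 of 13309 genes were called, 913 higher and 611 lower in CD5hi cells, and 372 of them differed by at least 2-fold. The blocked fit within states called 2396 genes, 1523 of the 1524 among them, and a fit on the fresh groups alone called 2183.

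Of the 23 TCR-induced genes, 13 were higher and 1 lower in fresh CD5hi cells (14 and 1 adjusted over the list alone). For TCR-induced genes the camera adjusted p was 1.7e-09, and adjusted p = 0.019 with an estimated correlation. Nr4a1, an orphan nuclear receptor induced by TCR signals, rose from 31.9 ± 2.99 to 69.5 ± 7.50 CPM (1.13 ± 0.11; edgeR adjusted p = 1.7e-07). Nr4a3 (0.83 ± 0.12), Egr1 (0.77 ± 0.17), Egr2 (0.68 ± 0.19), Egr3 (0.61 ± 0.14) and Cd200 (2.15 ± 0.15) were also higher, and Spry1 rose from 0.459 ± 0.0198 to 1.83 ± 0.182 CPM. The call on Egr2 was lost with DESeq2, at an adjusted p of 0.13, and in edgeR without fresh CD5lo replicate 1, 3 or 4 (0.051, 0.082 and 0.059) or fresh CD5hi replicate 2 or 3 (0.087 and 0.060). Over its alternatives the adjusted p ran from 8.3e-05 to 0.13. Irf4 did not pass, at -0.10 ± 0.21. Il2ra, the alpha chain of the interleukin 2 receptor, was lower in CD5hi cells (-0.84 ± 0.13).

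Among the 30 negative regulators of TCR signalling, 13 were higher and 2 lower (15 and 2 adjusted over the list alone). For negative regulators the camera adjusted p was 7.8e-10, and adjusted p = 1.2e-04 with an estimated correlation. Cd5, Folr4, Nt5e and the inhibitory receptor gene Pdcd1 (2.32 ± 0.20) were among the higher ones. Cd5 encodes the sort marker, so its place among the higher members, here and when rested, follows from the sort. Of 30 genes of the Treg signature, 16 were higher and 3 lower (18 and 3 adjusted over the list alone). For the Treg signature camera adjusted p was 3.4e-15, and adjusted p = 2.7e-04 with an estimated correlation. Ikzf2, which encodes Helios, rose by 2.45 ± 0.14, and Il2rb by 2.19 ± 0.09, whereas Foxp3 differed by 0.11 ± 0.06 and did not pass. The Treg list shares members with the other lists, among them Tnfrsf9 and Il2ra with the TCR-induced list and Ctla4, Tigit, Folr4 and Nt5e with the negative regulators.

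Recent thymic emigrant and thymocyte genes were lower in 6 and higher in 1 of 13 members (1 and 7 adjusted over the list alone). For thymocyte genes the camera adjusted p was 8.8e-05, and adjusted p = 0.0055 with an estimated correlation. Dntt, Cd8b1 and the chemokine receptor gene Ccr9 (-1.05 ± 0.16) fell, and Sox4 rose (1.10 ± 0.15). CD8, NK and gamma-delta markers fell in 4 of 8 members (1 and 5 adjusted over the list alone). For CD8 and NK markers camera adjusted p was 6.1e-04, and adjusted p = 0.013 with an estimated correlation. Cd8b1, which lies in both of these lists, was among them, as was Prf1, the perforin gene, at 41.4 ± 3.53 CPM in CD5lo and 20.7 ± 0.857 in CD5hi cells. Klrk1, an NK receptor gene, was lower too (-1.01 ± 0.30). That edgeR call was lost without fresh CD5lo replicate 2 or 3 (adjusted p = 0.11 and 0.056) or fresh CD5hi replicate 1, 3 or 4 (0.10, 0.061 and 0.084), and over its alternatives the adjusted p ran from 0.0035 to 0.11.

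Effector and memory genes rose in 6 and fell in 4 of 28 members (8 and 6 adjusted over the list alone; camera adjusted p = 0.10). Eomes (2.40 ± 0.23) and Id2 (1.98 ± 0.14), regulators of memory and effector differentiation, and the ATP-gated channel gene P2rx7 (2.05 ± 0.15) were higher, and Cd44 was lower (-0.60 ± 0.09). Cell cycle genes rose in 4 of 30 members (5 and 0 adjusted over the list alone), among them Mki67 (0.81 ± 0.17) and Top2a (0.94 ± 0.11). For cell cycle genes the camera adjusted p was 0.0012, and adjusted p = 0.086 with an estimated correlation. Genes of p53 and apoptosis rose in 5 of 19 members (6 and 0 adjusted over the list alone), and the camera adjusted p was 0.0043, and adjusted p = 0.20 with an estimated correlation. Bbc3 was among them (1.33 ± 0.18), as was Bcl2a1b, which has near-identical copies that can share its reads, from 3.91 ± 0.550 to 7.85 ± 1.27 CPM. Proximal TCR signalling components rose in 4 and fell in 5 of 24 members (4 and 7 adjusted over the list alone; camera adjusted p = 0.60). Their median change was 0.03 and their mean -0.02. Malt1 was higher (0.45 ± 0.04), and Grap2 (-0.60 ± 0.06) and Cd4 (-0.27 ± 0.04) were lower. Id3 was higher (0.89 ± 0.12) and Jun was lower (-1.86 ± 0.32).

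Rested CD5hi and CD5lo cells still differed, and 745 of the genes called when fresh were called the same way. Cd5 was higher in rested CD5hi cells by 2.29 ± 0.06 (edgeR adjusted p = 9.2e-17). Coro2a (2.68 ± 0.21), Folr4 (2.57 ± 0.08), Cd6, which encodes a receptor related to CD5 (2.43 ± 0.06), Lysmd2 (2.39 ± 0.12), Acvr1c (1.98 ± 0.17) and Cd200 (1.88 ± 0.16) were among the largest rises. Dntt (-3.20 ± 0.14), Pcsk1 (-3.13 ± 0.25), Car2 (-1.97 ± 0.21), Ly6c1 (-1.81 ± 0.25), Cd8b1 (-1.60 ± 0.10), Gprin3 (-1.59 ± 0.13) and the interferon-inducible GTPase gene Iigp1 (-1.44 ± 0.27) were among the largest falls. In all, 1092 genes were called, 631 higher and 461 lower in CD5hi cells, 272 by at least 2-fold. The blocked fit within states called 1961 genes, 1087 of the 1092 among them, and a fit on the rested groups alone called 495. In that fit the edgeR call on Iigp1 was lost (adjusted p = 0.057; 3.0e-10 to 0.057 over its alternatives). Rested replicates 3 and 4 alone, a setting added after seeing the data, called 639. The main fit shares 1 estimate of the spread over all groups, though libraries varied more when rested than when fresh. Fits on the compared groups alone called 2183 genes when fresh and 495 when rested. Counts of the 2 states are thus not directly comparable.

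TCR-induced genes were higher in 10 and lower in 1 of 23 members in rested CD5hi cells (11 and 1 adjusted over the list alone). For TCR-induced genes the camera adjusted p was 1.7e-09, and adjusted p = 0.019 with an estimated correlation. Tnfrsf9 (1.99 ± 0.16), Nr4a1 (1.56 ± 0.13), Nr4a3 (1.03 ± 0.15) and Bhlhe40 (1.83 ± 0.24) were higher. Egr1 (0.20 ± 0.18), Egr2 (0.67 ± 0.31), Egr3 (-0.30 ± 0.32) and Irf4 (-0.48 ± 0.21) did not pass in edgeR. Egr1 passed with rested replicates 1 and 2 alone, at 0.53 (adjusted p = 2.5e-04; 2.5e-04 to 1.0 over its alternatives). Irf4 passed, as lower, with the block within states (adjusted p = 3.1e-04), with rested replicates 3 and 4 alone (8.6e-04) and without rested CD5lo replicate 2 (0.045; 3.1e-04 to 0.66 over its alternatives). Il2ra was lower (-0.29 ± 0.08). Its edgeR call was lost in the fit on the rested groups, with female rested libraries only and with either pair of rested replicates. Leaving out rested CD5lo replicate 1, 3 or 4 (adjusted p = 0.063, 0.057 and 0.089) or rested CD5hi replicate 2 or 3 (0.12 and 0.056) ended it as well, with 3.4e-04 to 0.19 over the alternatives.

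Negative regulators rose in 8 and fell in 2 of 30 members in rested CD5hi cells (10 and 2 adjusted over the list alone), with Pdcd1 at 2.65 ± 0.26. For negative regulators the camera adjusted p was 7.2e-06, and adjusted p = 0.0012 with an estimated correlation. Treg signature genes rose in 16 and fell in 2 of 30 (19 and 3 adjusted over the list alone). For the Treg signature camera adjusted p was 1.4e-14, and adjusted p = 3.1e-04 with an estimated correlation. Nt5e (1.73 ± 0.12), Gpr83 (1.60 ± 0.14), Il2rb (1.43 ± 0.09) and Foxp3 (0.29 ± 0.06) were among the rises. The edgeR call on Foxp3 was lost in the fit on the rested groups (adjusted p = 0.065) and with rested replicates 3 and 4 alone (0.20; 1.1e-04 to 0.20 over its alternatives). Thymocyte genes fell in 5 and rose in 1 of 13 (1 and 6 adjusted over the list alone). For thymocyte genes the camera adjusted p was 5.0e-04, and adjusted p = 0.010 with an estimated correlation. CD8, NK and gamma-delta markers fell in 3 of 8 (0 and 3 adjusted over the list alone), Prf1 among them (-0.99 ± 0.10). For CD8 and NK markers camera adjusted p was 3.3e-05, and adjusted p = 0.0048 with an estimated correlation.

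Interferon-stimulated genes fell in 5 of 36 members in rested CD5hi cells (0 and 8 adjusted over the list alone), with Ly6a (-0.99 ± 0.12) and Igtp (-0.72 ± 0.12) as examples. For interferon-stimulated genes camera adjusted p was 2.4e-04, and adjusted p = 0.37 with an estimated correlation. Cell cycle genes rose in 8 and fell in 1 of 30 (10 and 1 adjusted over the list alone), with Mki67 (1.44 ± 0.19) and Cdk1 (1.08 ± 0.20). For cell cycle genes the camera adjusted p was 2.7e-04, and adjusted p = 0.052 with an estimated correlation. Cdkn1a, the gene of the cell cycle inhibitor p21, rose from 0.329 ± 0.0876 to 1.64 ± 0.588 CPM (2.32 ± 0.40). With rested replicates 1 and 2 alone, the edgeR calls on Cdk1 (adjusted p = 0.071; 8.1e-05 to 0.071 over its alternatives) and Cdkn1a (0.057; 4.1e-08 to 0.057) were lost. Cd4 (-0.28 ± 0.04) and Cd44 (-0.47 ± 0.10) were lower, the latter not in the fit on the rested groups (adjusted p = 0.11; 4.1e-06 to 0.11 over its alternatives). Genes of p53 and apoptosis rose in 4 of 19 (6 and 0 adjusted over the list alone), and the camera adjusted p was 6.3e-04, and adjusted p = 0.12 with an estimated correlation. Quiescence and homing genes fell in 2 of 24 (0 and 3 adjusted over the list alone), and the camera adjusted p was 0.017, and adjusted p = 0.42 with an estimated correlation.

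**Figure D2:**
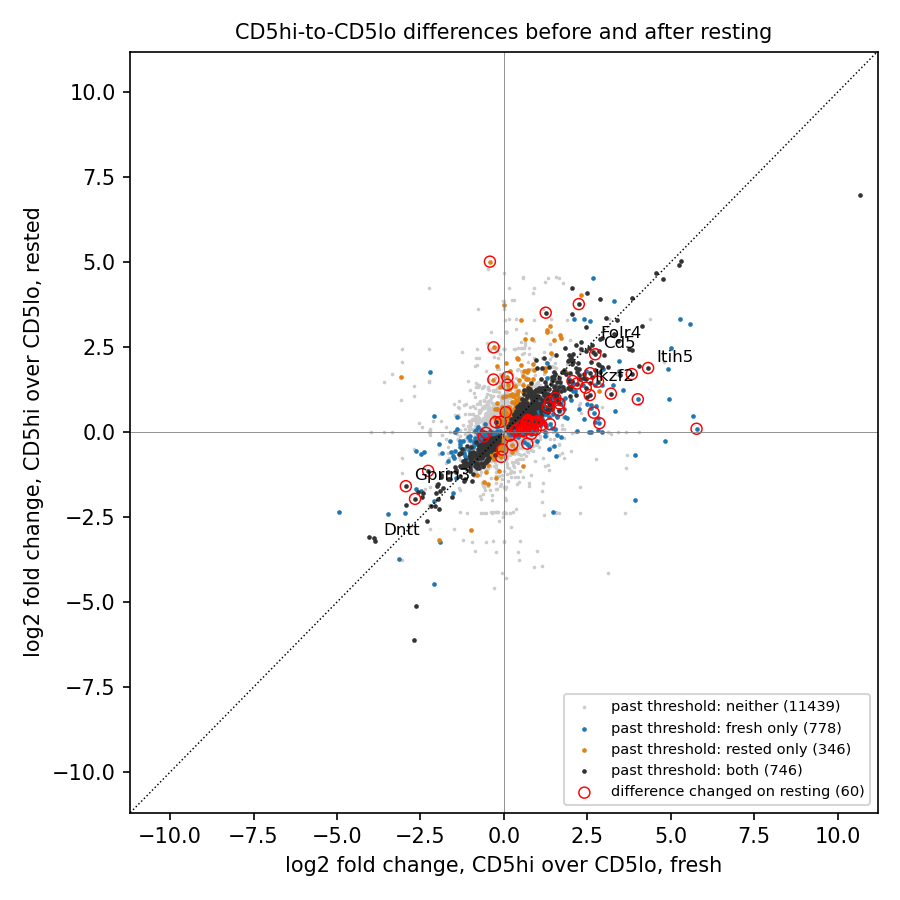
Log2 fold change of CD5hi over CD5lo cells when fresh (horizontal axis) and when rested (vertical axis) for 13309 genes, each point 1 gene, colored by which comparison called it, with the 60 interaction genes ringed. Cd5, Folr4 and Dntt lie far from 0 in both states, and the dotted line marks equal differences.

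Across the 13309 genes the fresh and rested differences correlated at Pearson's r = 0.506 ± 0.046 (jackknife SE over libraries) and Spearman's rho = 0.506, where genes are not independent replicates. The jackknife, here and below, drops single libraries and leaves their pairing aside. Every r without 1 library lay below 0.506, at 0.429 to 0.50, so the SE is no spread around that value. Of the 1524 genes called when fresh, 745, or 48.9% ± 4.48, were called the same way when rested, 95.9% had the same sign, and 1 was called the opposite way. The 48.9% depends on the estimate of the spread that all groups share. Shared calls numbered 436 for higher and 309 for lower genes, against 43.3 and 21.2 for independent lists of these sizes. The correlation was 0.166 without a filter on low counts and 0.664 for genes of at least 1 CPM in 4 libraries.

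The difference between CD5hi and CD5lo cells changed on resting in 60 genes by the interaction test, of which 50 were called when fresh and 47 differed less after resting in absolute size. The fresh difference was measured in libraries with Y-linked reads, the rested one mostly in libraries with Xist. A CD5 difference that depends on sex or preparation thus cannot be told apart from resting. Itih5 changed by -2.44 ± 0.18 (edgeR adjusted p = 7.6e-08), and stood at 36.9 ± 3.05 CPM in rested CD5lo and 136 ± 5.53 in rested CD5hi cells. Mtap6 (-2.08 ± 0.32), Qrfp (-1.48 ± 0.22), Fibcd1 (-1.34 ± 0.22) and Adamtsl4 (-1.15 ± 0.15) also had negative changes. Gprin3 (1.35 ± 0.20), Rxra (0.54 ± 0.10), Mtmr3 (0.53 ± 0.08), Cd7 (0.51 ± 0.10) and Pou6f1 (0.47 ± 0.10) had positive ones. Of 30 negative regulators, 4 had negative changes (1 and 7 adjusted over the list alone), namely Nt5e (-0.85 ± 0.17), Ctla4 (-0.80 ± 0.16), Ubash3b (-0.50 ± 0.09) and Cd5 (-0.45 ± 0.08). For negative regulators the camera adjusted p was 2.3e-04, and adjusted p = 0.0055 with an estimated correlation. In the Treg signature 6 of 30 had negative changes (3 and 10 adjusted over the list alone), among them Ikzf2 (-1.15 ± 0.21), Ikzf4 (-1.02 ± 0.14), Nrp1 (-0.91 ± 0.19) and Il2rb (-0.76 ± 0.13). For the Treg signature camera adjusted p was 9.1e-04, and adjusted p = 0.059 with an estimated correlation. Fosb, an immediate early gene, had a positive change (1.51 ± 0.33). Over all genes edgeR called 60, the block within states 247 with all 60 among them, and DESeq2 130, and 848 had an unadjusted p under 0.05. Leaving out fresh CD5hi replicate 2 gave 36 calls, and leaving out fresh CD5lo replicate 1 or 4 or rested CD5hi replicate 1 gave 39.

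Several of these edgeR calls were lost without a single library. Cd7 lost its call without fresh CD5lo replicate 1, fresh CD5hi replicate 2 or 3, rested CD5lo replicate 4 or rested CD5hi replicate 1 (adjusted p = 0.055 to 0.071; 9.1e-04 to 0.11 over its alternatives). Ctla4 did so without fresh CD5lo replicate 1 or 4 or fresh CD5hi replicate 2 (0.051 to 0.064; 3.1e-04 to 0.34). Nt5e did so without fresh CD5lo replicate 4, fresh CD5hi replicate 2, 3 or 4, rested CD5lo replicate 4 or rested CD5hi replicate 1 (0.050 to 0.079; 1.6e-04 to 0.19). Nrp1 did so without fresh CD5lo replicate 1, 2 or 4, fresh CD5hi replicate 2 or 3, rested CD5lo replicate 3 or 4 or rested CD5hi replicate 2 (0.059 to 0.091; 2.0e-04 to 0.10). Pou6f1 lost it without any one of 11 naive libraries (0.058 to 0.088; 0.0011 to 0.088), and kept it without fresh CD5lo replicate 1, fresh CD5hi replicate 4, rested CD5lo replicate 1 or 2 or rested CD5hi replicate 3. Fosb lost it without any one of 13 (0.051 to 0.11; 0.0041 to 0.20), and kept it without fresh CD5hi replicate 1, rested CD5lo replicate 2 or rested CD5hi replicate 2. Mtap6 was not called by limma-voom (adjusted p = 0.24; 3.8e-09 to 0.24 over its alternatives), nor Ikzf2 in the fit on the naive groups (0.076) or with rested replicates 3 and 4 alone (0.12; 6.4e-07 to 0.12). Rxra was not called with female rested libraries only (0.051) or with rested replicates 3 and 4 alone (0.086; 1.7e-04 to 0.086).

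Of the 23 TCR-induced genes, edgeR called 0 for the interaction over all genes (3 and 3 adjusted over the list alone), with 11 at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma-voom. Nr4a1 changed by 0.44 ± 0.17, Nr4a3 by 0.20 ± 0.19, Egr1 by -0.57 ± 0.25, Egr2 by -0.01 and Egr3 by -0.91 ± 0.35, none past the threshold. No SE is given for Egr2, whose change is too near 0 for it. With the block within states Nr4a1 passed in edgeR (adjusted p = 0.022; 0.022 to 0.96 over its alternatives). Egr1 passed with that block (0.016) and with rested replicates 3 and 4 alone (0.0043; 0.0043 to 1.0). Egr3 passed without rested CD5hi replicate 3 (0.038; 0.038 to 1.0).

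The TCR-induced genes Egr1, Egr2, Egr3, Nr4a1 and Nr4a3 and most interferon-stimulated genes were lower, and most cytokine and STAT5 response genes higher, in rested than in fresh cells of both CD5 groups. Egr3 fell from 13.8 ± 1.42 to 0.373 ± 0.148 CPM in CD5lo cells (-5.18 ± 0.21; edgeR adjusted p = 1.3e-14) and from 21.1 ± 1.23 to 0.301 ± 0.192 in CD5hi cells (-6.10 ± 0.22; adjusted p = 1.8e-15). Egr2 (-4.01 ± 0.26 in CD5lo and -4.01 ± 0.24 in CD5hi cells), Nr4a1 (-3.56 ± 0.13 and -3.12 ± 0.12), Egr1 (-2.56 ± 0.18 and -3.13 ± 0.19) and Nr4a3 (-2.06 ± 0.14 and -1.86 ± 0.13) fell as well. Irf4 rose in CD5lo cells (0.63 ± 0.20). That edgeR call was lost without rested CD5lo replicate 4 (adjusted p = 0.11) and with rested replicates 1 and 2 alone (0.86; 5.1e-09 to 0.86 over its alternatives). In CD5hi cells Irf4 did not pass (0.26 ± 0.21), but did in male libraries, with 1 rested library (0.58, adjusted p = 0.0011), and with rested replicates 3 and 4 alone (0.56, adjusted p = 3.7e-05; 3.7e-05 to 0.67 over its alternatives). Of the TCR-induced list, 7 rose and 10 fell in CD5lo cells (7 and 12 adjusted over the list alone; camera adjusted p = 0.41), and 7 rose and 13 fell in CD5hi cells (7 and 14 adjusted over the list alone; camera adjusted p = 0.23). Il2ra is in that list and rose, from 2.93 ± 0.463 to 108 ± 4.62 CPM in CD5lo cells (5.20 ± 0.11) and from 1.64 ± 0.308 to 88.6 ± 8.89 in CD5hi cells (5.75 ± 0.11).

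**Figure D3:**
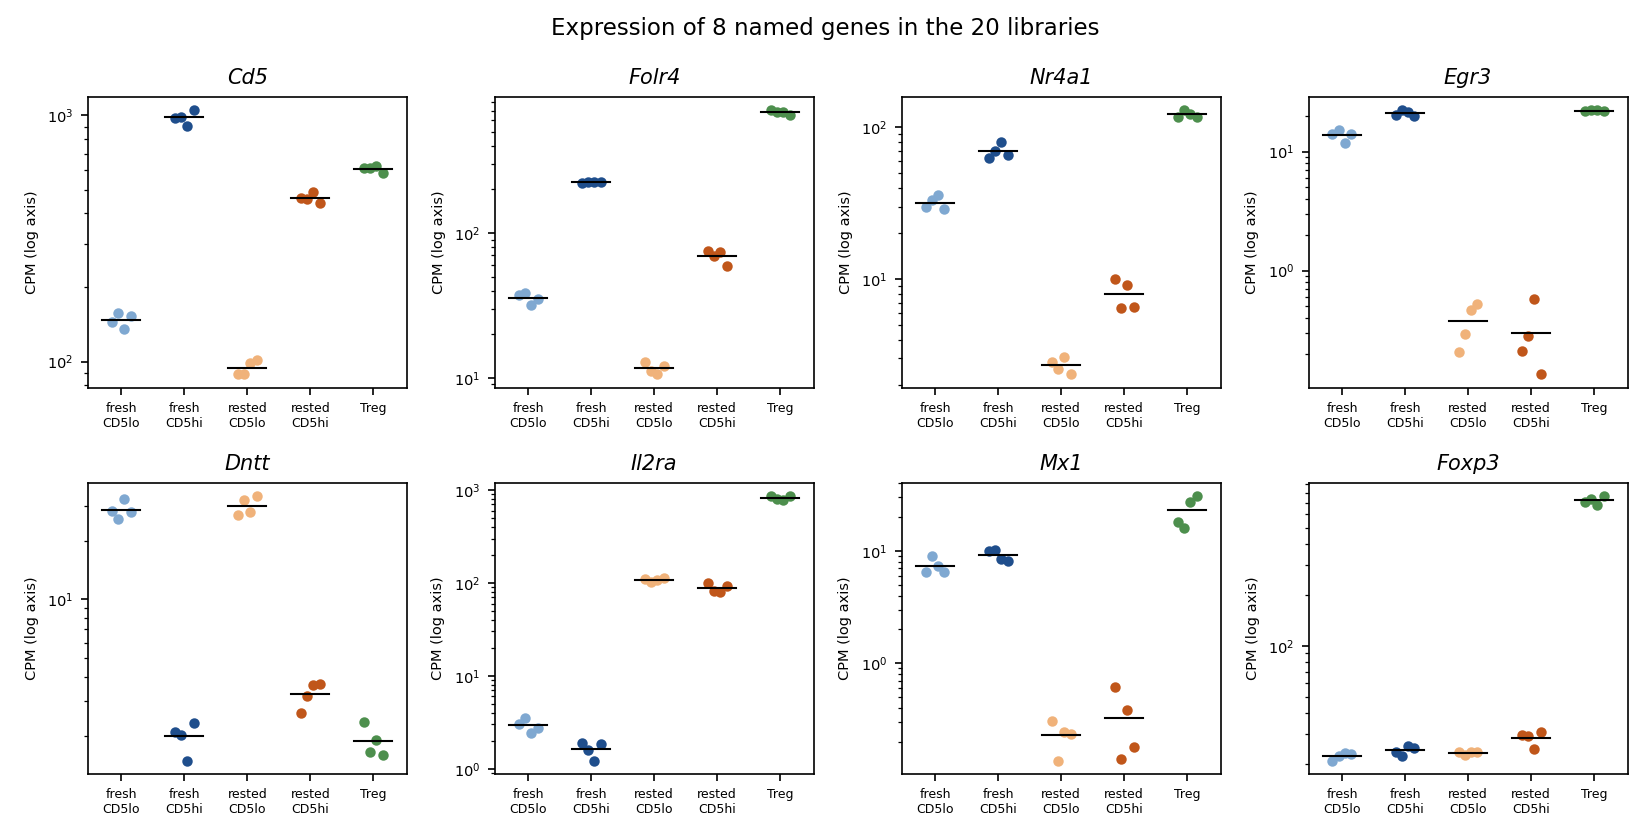
CPM of 8 genes in the 20 libraries by group, on a log axis, with 1 point per library and a bar at the mean of the 4. Egr3, Nr4a1 and Mx1 are lower and Il2ra higher in the rested groups, and Foxp3 is highest in Treg at 722 CPM.

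Of the 23 cytokine and STAT5 response genes, 16 rose and 1 fell in CD5lo cells (16 and 2 adjusted over the list alone), and 18 rose and 3 fell in CD5hi cells (18 and 3 adjusted over the list alone). For STAT5 genes the camera adjusted p was 1.1e-08 and 9.8e-09, and adjusted p = 2.4e-04 and 2.4e-04 with an estimated correlation. Socs2, a feedback inhibitor of cytokine signalling, rose by 6.14 ± 0.20 and 6.88 ± 0.21 in CD5lo and CD5hi cells. Bcl2, a survival factor, rose by 2.90 ± 0.10 and 2.40 ± 0.10, Pim1, a kinase gene, by 2.59 ± 0.05 and 2.54 ± 0.05, and Cdkn1a by 4.35 ± 0.49 in CD5hi cells. Of 36 interferon-stimulated genes, 31 fell and 2 rose in CD5lo cells (2 and 31 adjusted over the list alone), and 32 fell and 1 rose in CD5hi cells (1 and 32 adjusted over the list alone). For interferon-stimulated genes the camera adjusted p was 1.4e-15 and 3.4e-18, and adjusted p = 0.044 and 0.030 with an estimated correlation. Mx1 changed by -4.96 ± 0.31 and -4.85 ± 0.30, Rsad2 by -3.31 ± 0.19 and -3.67 ± 0.19, and Ifi44 by -2.94 ± 0.27 and -3.34 ± 0.28. Mx2 changed by -3.05 ± 0.17 and -3.17 ± 0.17. The Treg signature rose in 15 and fell in 2 of 30 in CD5lo cells (15 and 2 adjusted over the list alone) and rose in 16 and fell in 4 in CD5hi cells (16 and 4 adjusted over the list alone). It shares Il2ra, Il2rb and Socs2 with the cytokine and STAT5 list, so the results of these lists overlap. For the Treg signature the camera adjusted p was 1.8e-04 and 0.0010, and adjusted p = 0.037 and 0.060 with an estimated correlation. Ctla4 rose by 4.18 ± 0.12 and 3.38 ± 0.11, and Rgs1 by 4.57 ± 0.34 and 4.00 ± 0.31. Foxp3 differed by 0.06 ± 0.06 in CD5lo cells, which did not pass, and by 0.25 ± 0.06 in CD5hi cells. The latter edgeR call ended with sex as a covariate (0.15, adjusted p = 0.072) and in male libraries, with 1 rested library (0.04, adjusted p = 0.68; 7.7e-05 to 0.68 over its alternatives).

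Cholesterol biosynthesis genes rose in 16 and fell in 1 of 23 in CD5lo cells (16 and 1 adjusted over the list alone) and rose in 17 and fell in 1 in CD5hi cells (17 and 1 adjusted over the list alone). For cholesterol genes the camera adjusted p was 2.9e-06 and 2.3e-07, and adjusted p = 0.086 and 0.060 with an estimated correlation. Acat2 (1.54 ± 0.08 and 1.58 ± 0.08) and Insig1 (1.29 ± 0.10 in CD5lo) were among them. Genes of p53 and apoptosis rose in 12 and 14 and fell in 2 and 1 of 19 in CD5lo and CD5hi cells (12 and 2 adjusted over the list alone, and 15 and 1 adjusted over the list alone). For p53 genes the camera adjusted p was 0.0015 and 4.0e-04, and adjusted p = 0.15 and 0.11 with an estimated correlation. Phlda3 (2.16 ± 0.31 and 2.21 ± 0.29), Bcl2l11, which encodes the pro-apoptotic protein Bim (1.49 ± 0.07 and 1.27 ± 0.07), and Bbc3 (1.32 ± 0.18 in CD5lo) rose. Quiescence and homing genes rose in 16 and 13 and fell in 4 and 4 of 24 (16 and 4 adjusted over the list alone, and 14 and 4 adjusted over the list alone). For quiescence genes the camera adjusted p was 0.0012 and 0.023, and adjusted p = 0.25 and 0.45 with an estimated correlation. Klf2 (1.25 ± 0.08 and 0.96 ± 0.07) and Slfn2 (1.23 ± 0.13 and 1.21 ± 0.13) rose, and Foxo1 fell (-1.19 ± 0.07 and -1.13 ± 0.07). Proximal TCR components fell in 16 and 16 and rose in 4 and 4 of 24 (5 and 16 adjusted over the list alone, and 4 and 16 adjusted over the list alone). For proximal components the camera adjusted p was 0.022 and 0.016, and adjusted p = 0.059 and 0.048 with an estimated correlation. Cd3g was lower (-0.55 ± 0.06 and -0.70 ± 0.06), and Trat1 (1.18 ± 0.13 and 1.22 ± 0.13) and Rasgrp1 (1.08 ± 0.09 and 0.99 ± 0.09) were higher. Negative regulators rose in 7 and fell in 16 of 30 in CD5hi cells (7 and 16 adjusted over the list alone), and the camera adjusted p was 0.024, and adjusted p = 0.058 with an estimated correlation.

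Mtap6 (7.46 ± 0.22 and 5.38 ± 0.17), Ecm1 (5.43 ± 0.08 and 4.78 ± 0.08), Gpr34 (5.21 ± 0.14 and 5.25 ± 0.14) and Trib3 (3.04 ± 0.09 and 3.28 ± 0.10) were among the other rises. Slc16a5 (-4.81 ± 0.17 and -4.91 ± 0.19), the Notch regulator Dtx1 (-4.43 ± 0.19 and -4.86 ± 0.19), Abca1 (-3.75 ± 0.15 and -4.09 ± 0.16) and P2rx7 (-3.61 ± 0.20 and -3.54 ± 0.17) fell. So did Ddit4 (-2.92 ± 0.19 and -3.11 ± 0.19), Bcl6 (24.7 ± 1.93 to 6.18 ± 0.864 CPM in CD5lo cells and -2.23 ± 0.10 in CD5hi cells) and Cd44 (-1.48 ± 0.09 and -1.36 ± 0.10). Cd5 changed by -0.64 ± 0.06 and -1.09 ± 0.06, and Folr4 by -1.69 ± 0.07 in CD5hi cells. In all, 7221 genes were called in CD5lo cells, 3582 up and 3639 down on resting, and 6978 in CD5hi cells, 3486 up and 3492 down. Rises outnumbered falls in CD5lo cells with male libraries (3435 and 3162), rested replicates 3 and 4 alone (3852 and 3812) and only the groups compared (3405 and 3398). They did so in CD5hi cells with male libraries (3616 and 3360), rested replicates 3 and 4 alone (3608 and 3561) and without fresh CD5hi replicate 4 (3154 and 3151) or rested CD5hi replicate 4 (3287 and 3264). The changes correlated across genes at r = 0.846 ± 0.025 and rho = 0.858, and at r = 0.542 without a filter on low counts. Without 1 library r was 0.801 to 0.837, always below 0.846, so here too the SE is no spread around the value. Genes that rose in both numbered 3007 and those that fell in both 2967, against 938 and 955 for independent lists, with 8 called in opposite directions. With male libraries only, which leaves 1 rested library per CD5 group, assumed to vary like the fresh ones, 6597 genes were called in CD5lo cells and 6976 in CD5hi cells, and r was 0.696.

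**Figure D4:**
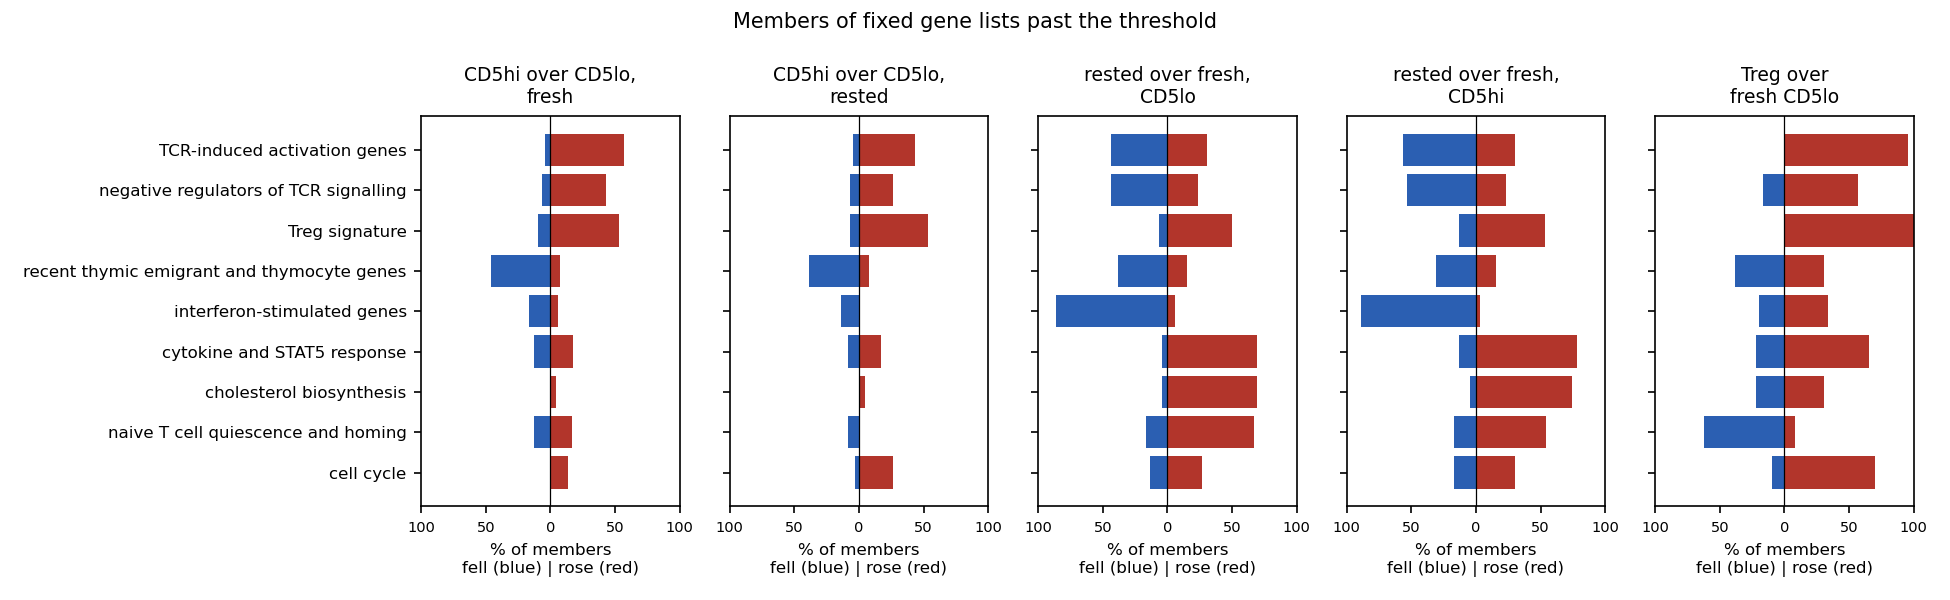
Share of the measured members of 9 fixed gene lists called higher (red, right) or lower (blue, left), in percent, in 5 comparisons. Interferon-stimulated genes stand out as lower in rested cells, and cytokine and STAT5 genes as higher.

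Transcripts of macrophages and red cells were also lower in rested cells. Myeloid and granulocyte markers fell in 11 and rose in 1 of 17 in CD5lo cells (1 and 11 adjusted over the list alone) and fell in 11 in CD5hi cells (1 and 11 adjusted over the list alone). For myeloid markers the camera adjusted p was 2.3e-04 and 7.6e-05, and adjusted p = 0.11 and 0.086 with an estimated correlation. Csf1r, the macrophage growth factor receptor gene, averaged 4.42 ± 0.83 and 3.21 ± 0.818 CPM in fresh and 0.0526 ± 0.0659 and 0.0677 ± 0.0605 CPM in rested CD5lo and CD5hi cells. C1qb averaged 2.11 ± 0.362 and 1.77 ± 0.291 CPM when fresh, with 2 counts in rested CD5lo cells and 0 in rested CD5hi cells, where 3 counts would be 0.0167 CPM. C1qa averaged 1.94 ± 0.233 and 1.64 ± 0.772 CPM when fresh, with 0 counts in rested CD5lo cells, where 3 counts would be 0.0156 CPM, and 2 in rested CD5hi cells. Erythroid and platelet markers fell in 10 of 12 in CD5lo and fell in 9 and rose in 1 in CD5hi cells (0 and 10 adjusted over the list alone, and 1 and 10 adjusted over the list alone). For erythroid markers the camera adjusted p was 0.0073 and 0.0096, and adjusted p = 0.42 and 0.44 with an estimated correlation. Hbb-b1, which shares its reads with Hbb-b2, averaged 10.5 ± 4.05 and 8.05 ± 2.96 CPM when fresh and 0.684 ± 0.833 and 0.651 ± 0.933 when rested. CD8, NK and gamma-delta markers fell in 4 and 5 of 8 (0 and 4 adjusted over the list alone, and 0 and 5 adjusted over the list alone). For CD8 and NK markers the camera adjusted p was 0.049 and 0.043, and adjusted p = 0.12 and 0.11 with an estimated correlation, and the first call was lost with the replicate block common to all groups (adjusted p = 0.054). B cell markers rose in 6 and 9 and fell in 2 and 2 of 12 (7 and 2 adjusted over the list alone, and 9 and 2 adjusted over the list alone; camera adjusted p = 0.13 and 0.11). Ms4a1 was at 0.426 and 0.273 CPM when fresh and 1.15 and 1.38 when rested in CD5lo and CD5hi cells.

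Treg differed from both naive groups in the Treg signature, of which 30 and 30 of 30 genes were higher against fresh CD5lo and CD5hi cells (30 and 0 adjusted over the list alone, and 30 and 0 adjusted over the list alone). For the Treg signature the camera adjusted p was 1.5e-25 and 1.5e-25, and adjusted p = 3.3e-05 and 3.3e-05 with an estimated correlation. Foxp3 was higher by 5.01 ± 0.07 against CD5lo (edgeR adjusted p = 2.3e-22) and 4.91 ± 0.07 against CD5hi. Il2ra was higher by 8.13 ± 0.12 and 8.97 ± 0.12, Ctla4 by 7.81 ± 0.13 and 6.94 ± 0.12, and Tigit by 8.33 ± 0.26 and 7.30 ± 0.24. Socs2 was higher by 8.47 ± 0.20 and 8.87 ± 0.21, and Il2rb by 7.26 ± 0.11 and 5.07 ± 0.10. Against CD5lo cells Ikzf2 was higher by 8.99 ± 0.15 and Tnfrsf9 by 6.51 ± 0.12. Lrrc32, the surface receptor for latent TGF-beta on Treg, averaged 461 ± 32.3 CPM in Treg, with 2 counts in fresh CD5lo and 17 in fresh CD5hi cells. Penk averaged 40.6 ± 4.57 CPM with 2 counts in fresh CD5lo cells, and Klrg1 42.8 ± 7.04 CPM with 2 counts in fresh CD5hi cells. Cd5 in Treg was higher than in CD5lo cells (2.04 ± 0.06) and lower than in CD5hi cells (-0.70 ± 0.06).

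TCR-induced genes were higher in Treg in 22 and 19 of 23 against CD5lo and CD5hi cells (22 and 0 adjusted over the list alone, and 19 and 0 adjusted over the list alone). For TCR-induced genes the camera adjusted p was 2.6e-11 and 5.4e-09, and adjusted p = 0.010 and 0.022 with an estimated correlation. Cytokine and STAT5 genes, which share Il2ra, Il2rb and Socs2 with the Treg signature, rose in 15 and 15 and fell in 5 and 4 of 23 (16 and 5 adjusted over the list alone, and 15 and 4 adjusted over the list alone). For STAT5 genes the camera adjusted p was 6.7e-04 and 4.0e-04, and adjusted p = 0.010 and 0.0082 with an estimated correlation. Negative regulators rose in 17 and fell in 5 of 30 against CD5lo cells (17 and 5 adjusted over the list alone), and the camera adjusted p was 1.0e-03, and adjusted p = 0.010 with an estimated correlation. The effector list, which shares Il2rb and Prdm1 with the Treg signature, rose in 23 and 22 and fell in 2 and 3 of 28 (24 and 2 adjusted over the list alone, and 22 and 3 adjusted over the list alone). For effector genes the camera adjusted p was 8.0e-08 and 5.7e-07, and adjusted p = 0.15 and 0.19 with an estimated correlation. S100a4 (8.17 ± 0.32 and 7.08 ± 0.30) and Cd44 (2.07 ± 0.09 and 2.66 ± 0.10) were among them. Cell cycle genes rose in 21 and 20 and fell in 3 and 3 of 30 (21 and 3 adjusted over the list alone, and 20 and 3 adjusted over the list alone), with Mki67 at 3.52 ± 0.18 and 2.71 ± 0.17. For cell cycle genes the camera adjusted p was 2.0e-04 and 0.0023, and adjusted p = 0.048 and 0.10 with an estimated correlation. Genes of p53 and apoptosis rose in 15 and 13 and fell in 1 and 2 of 19 (16 and 1 adjusted over the list alone, and 14 and 3 adjusted over the list alone). For p53 genes the camera adjusted p was 1.3e-04 and 0.0023, and adjusted p = 0.086 and 0.17 with an estimated correlation.

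Lower in Treg were Ggt5 (-7.79 ± 0.16 and -7.50 ± 0.16), Pdlim4 (-8.73 ± 0.31 and -6.86 ± 0.31) and the phosphodiesterase gene Pde3b (-5.62 ± 0.12 and -4.88 ± 0.12), and Dapl1 against CD5hi cells (-5.14 ± 0.15). Quiescence and homing genes fell in 15 and 16 and rose in 2 and 2 of 24 (2 and 16 adjusted over the list alone, and 2 and 17 adjusted over the list alone). For quiescence genes the camera adjusted p was 1.4e-04 and 7.9e-06, and adjusted p = 0.16 and 0.10 with an estimated correlation. The transcription factor genes Tcf7 (-2.07 ± 0.08 and -1.96 ± 0.08), Satb1 (-1.90 ± 0.07 and -1.95 ± 0.07) and Lef1 (-1.60 ± 0.06 and -1.82 ± 0.06), Ccr7 (-1.44 ± 0.05 against CD5lo) and Il7r (-1.49 ± 0.15 against CD5hi) were among them. Proximal TCR components fell in 17 and 18 and rose in 4 and 3 of 24 (4 and 18 adjusted over the list alone, and 3 and 19 adjusted over the list alone). For proximal components the camera adjusted p was 4.2e-04 and 5.7e-05, and adjusted p = 0.0082 and 0.0036 with an estimated correlation. Themis was lower (-2.33 ± 0.06 and -2.00 ± 0.06), and so was Dntt against CD5lo cells (-3.92 ± 0.14). Treg and fresh CD5lo cells differed in 7791 genes, 3881 higher and 3910 lower in Treg, and Treg and fresh CD5hi cells in 7208, 3663 higher and 3545 lower. Sex differed between Treg and fresh cells too, and any difference of day or library preparation between them cannot be told apart from cell type. Against CD5lo cells lower genes also outnumbered higher ones with the replicate block common to all groups (3954 higher and 4036 lower) and by limma-voom (3919 and 3972), but higher ones outnumbered lower ones under all other alternatives run. These were DESeq2 size factors in edgeR (4081 and 3523), DESeq2 (4114 and 3581), no filter on low counts (4206 and 3573), the stricter filter (3607 and 3354), sex as a covariate (3770 and 3767), male libraries (3568 and 2997), only the groups compared (4200 and 3932) and leaving out any one of the 8 libraries (3799 to 3914 higher and 3408 to 3500 lower). Against CD5hi cells higher genes outnumbered lower ones under all alternatives run, with 3863 and 3190 by DESeq2 size factors in edgeR. Male libraries alone, with 1 Treg library assumed to vary like the fresh ones, called 6565 and 6025.

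Markers of other cells moved with these comparisons. B cell markers rose in 10 of 12 in Treg against both (10 and 0 adjusted over the list alone, and 10 and 0 adjusted over the list alone). For B cell markers the camera adjusted p was 0.0041 and 0.0010, and adjusted p = 0.20 and 0.15 with an estimated correlation. Cd79b averaged 17.2 ± 0.987 CPM in Treg against 0.738 ± 0.161 and 0.699 ± 0.292 in fresh CD5lo and CD5hi cells. The MHC class II chain gene Cd74 was higher by 3.22 ± 0.21 and 3.49 ± 0.21. Erythroid and platelet markers fell in 11 of 12 against CD5lo cells (0 and 11 adjusted over the list alone), and the camera adjusted p was 0.016, and adjusted p = 0.49 with an estimated correlation. CD8, NK and gamma-delta markers fell in 5 and rose in 1 of 8 there (1 and 5 adjusted over the list alone), and the camera adjusted p was 0.043, and adjusted p = 0.11 with an estimated correlation.

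Genes that separate CD5hi from CD5lo cells also tended to separate Treg from CD5lo cells. Of the 913 genes higher in fresh CD5hi cells, 667 were higher and 109 lower in Treg, and of the 611 lower ones 384 were lower and 132 higher. Calls in the same direction thus numbered 1051, against 446 for independent lists, which leave out the shared libraries. Simulated unchanged groups compared with a shared CD5lo group had a mean of 0 shared calls by the likelihood-ratio test of edgeR at the adjusted threshold. Groups without changed genes are bound to give few such calls, and independent lists gave 0 as well, so this 0 sets no level for the 1051. At an unadjusted p under 0.05 they shared 122, against 17.2 for independent lists, so a shared CD5lo group alone raised the count. With the CD5lo libraries split between the comparisons, 681 to 745 calls were shared in direction and 130 to 154 were opposite, against 244 to 279.6 shared for independent lists. For rested CD5hi against CD5lo and Treg against fresh CD5lo, which share no library, 746 were shared in direction and 184 opposite, against 319 shared for independent lists. The changes of the fresh comparison and of Treg correlated at r = 0.439 ± 0.022 with a covariance of 0.356. Both comparisons use the same CD5lo libraries. Unchanged simulated groups gave r = 0.480 and a covariance of 0.0349, and the covariance exceeded that by 0.321. With the CD5lo libraries split between the comparisons, r was 0.371 to 0.411 and the covariance 0.340 to 0.390. Between the rested CD5hi-to-CD5lo difference and Treg against fresh CD5lo, r was 0.340 and the covariance 0.282.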

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

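The tests on sex, on replicates 1 and 2 against 3 and 4, on a uniform loss of differences and on calls shared by fresh and rested libraries, and the counts of splits, were chosen only after the results were seen; the macrophage list and the averaged difference were set before. For the averaged difference, the margin that its spread had to clear was set after its value was known.

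Named genes were examined in 397 groups of 4 libraries for a library whose gap to the nearest other takes up most of the range of the 4. In all, 23 were found where chance gives about 19.9. Of these, 8 lay in rested replicate 3, the rested pair with Y-linked reads. In rested CD5hi replicate 3, Adamtsl4 was at 82.5 CPM, C1qa at 0.0426, Cd6 at 558, Gprin3 at 8.24, Nr4a3 at 3.51 and Pou6f1 at 58.5, and in rested CD5lo replicate 3, Cd3g was at 334 and Socs2 at 11.8. The other rested ones were C1qb at 0.0337 CPM in CD5lo replicate 4, Foxp3 at 22.6 in CD5lo replicate 2 and Tnfrsf9 at 1.91 in CD5hi replicate 2. In fresh CD5lo libraries, Adamtsl4 was at 7.75 CPM, Pde3b at 289.9 and Rasgrp1 at 546 in replicate 3, Cd7 at 43.3 and Hbb-b1 at 16.6 in replicate 1, and Qrfp at 0.680, Lrrc32 at 0.0340 and Penk at 0.0340 in replicate 2. In fresh CD5hi libraries, Dapl1 was at 103.9 and Malt1 at 212 CPM in replicate 2, and Klrg1 at 0.0333 and Mki67 at 7.12 in replicate 4. The rule weighs the gap only against the range, so small differences are flagged too, such as Cd3g at 334 against 341 and 342 CPM. It also takes genes with counts in 1 library of the group alone, such as Penk.

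The CD5hi-to-CD5lo difference changed on resting, by the interaction test, for 19 named genes. The rested minus fresh differences were -2.44 for Itih5, -2.08 for Mtap6, -1.48 for Qrfp, -1.34 for Fibcd1, -1.15 for Adamtsl4, -0.85 for Nt5e, -0.80 for Ctla4, -0.50 for Ubash3b, -0.45 for Cd5, -1.15 for Ikzf2, -1.02 for Ikzf4, -0.91 for Nrp1 and -0.76 for Il2rb. They were 1.35 for Gprin3, 0.54 for Rxra, 0.53 for Mtmr3, 0.51 for Cd7, 0.47 for Pou6f1 and 1.51 for Fosb.

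Of the 60 interaction genes, 47 differed less after resting. Selection of genes whose fresh difference was overestimated may contribute. Among 2305 genes called on the difference averaged over both states, 61.6% differed less after resting, but leaving out 1 library moved that share from 49.1 to 65.0%, so the asymmetry and this selection cannot be told apart. A uniform loss of differences, such as mixing of the sorts, would not by itself give the 7 interaction genes with a larger difference of the same sign after resting. Such a loss can act beside changes of single genes, so these 7 do not exclude it as a part of the cause. Over the 2305 genes the ratio of the rested to the fresh difference had a median of 0.848 and quartiles of 0.576 and 1.25. A biological loss of CD5-linked differences in culture stays open, as does a CD5 difference that depends on sex or preparation. Sex as a covariate shifts both CD5 groups alike and cannot adjust for the latter.

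Genes changed by resting in both CD5 groups number 5974, and sex and replicate structure differ between the groups. With sex as a covariate the median ratio of the adjusted to the unadjusted change was 1.08 in both CD5 groups, with quartiles of 0.957 and 1.23 over both, which argues against sex as the whole cause. A difference between replicates 1 and 2 and replicates 3 and 4 as the cause is argued against by separate fits, which share no library: for 5125 genes called with fresh and rested replicates 1 and 2, the median ratio of the change in 3 and 4 to that in 1 and 2 was 1.11 in CD5lo and 1.08 in CD5hi cells, and for 4358 genes called with 3 and 4 the converse ratio was 0.716 and 0.735, with lower quartiles of 0.493 and 0.520. Any difference of day or library preparation between fresh and rested groups cannot be told apart from resting, and the loss of self-peptide, the added interleukin 7 and culture itself were not separated by the design.

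Macrophage and red cell transcripts were higher in fresh than in rested cells. RNA of macrophages in the fresh sorts is a candidate explanation, since all 18 of the measured genes of a further macrophage list fell in both CD5 groups, although the sort excluded cells with F4/80 or CD11b. The most abundant of them were Lgmn at 20.2, Sdc3 at 16.1 and Apoe at 11.1 CPM in fresh CD5lo cells, while Vcam1 went from 4.31 to 0.0103 CPM, and 5 of the 18 stayed at 1 CPM or more in rested CD5lo cells and 8 in Treg, where Maf was at 172 CPM. Some members likely passed the expression filter through the fresh groups alone, so their fall was nearly fixed in advance. Timd4, for example, was at 0.264 and 0.213 CPM in fresh CD5lo and CD5hi cells and at 0 in both rested groups. Cd163 differed between the CD5 groups, at 3.88 and 0.784 CPM when fresh and 1.95 and 0.317 when rested in CD5lo and CD5hi cells. Sex as the whole cause is argued against by the fit with sex as a covariate, in which the ratio of the adjusted to the unadjusted change over 19 myeloid and erythroid members that fell had a median of 0.932 in CD5lo and 0.951 in CD5hi cells and lower quartiles of 0.634 and 0.732. Whether such cells were lost in culture was not tested.

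Other splits of the same libraries tested whether chance assignment gives as many edgeR calls. For fresh CD5hi against CD5lo, 1 of 35 splits, the real one, gave 1524 or more, and the highest other gave 1. Among the 8 of these that part all 4 pairs, the highest other gave 0, and 8 are too few for a share under 0.05. Resting called 7221 genes in CD5lo and 6978 in CD5hi cells, and Treg differed from CD5lo in 7791 and from CD5hi in 7208. In each, 1 of 35 splits, the real one, gave as many, a share of 0.0286, the lowest that 35 splits allow. The highest other gave 0 at the adjusted threshold. Each other split mixes groups that differ in many genes, which widens its spread, so 0 calls were likely in advance. The 0 thus adds nothing to the share, and these splits do not by themselves exclude chance. For rested CD5hi against CD5lo, 5 of 35 gave 1092 or more, so these splits, which leave the pairs aside, do not by themselves exclude chance. The highest other, 3539, set replicates 1 and 2 of both CD5 groups against 3 and 4, a structure of the rested libraries. Among the 8 splits that part all 4 pairs, the real one called 1092 and the highest other 0, but 8 splits are too few for a share under 0.05, and the blocked count was 1961. Chance assignment in either state is argued against by the other state, whose libraries are different: 745 genes were called the same way in fresh and rested cells, where independent lists would share 64.5, and 1 was called the opposite way. For the interaction, 4 of 100 drawn splits gave 60 or more and the highest other gave 539, several times the real count. That split kept 3 of the 4 CD5lo labels of fresh cells and 0 of those of rested cells, and all 3 of the other splits with as many calls kept more labels in 1 state than in the other, which leaves part of the CD5 difference itself in the count. Of the drawn splits, 5 others parted all pairs in both states, with at most 33 calls, too few for a share under 0.05. The splits thus do not settle whether chance gives 60 calls.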

How the results depend on the processing

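Alternatives added only after the results were seen were the block within states, the sex covariate, male or female libraries only, pairs of rested replicates and, for named genes, the filters on low counts; the others were set before. Of 241 results for named genes, 216 kept their call under every alternative run, 25 changed it under at least 1, and none changed direction past the threshold. The block within states moved the calls of CD5hi against CD5lo to 2396 when fresh and 1961 when rested and the interaction to 247. It kept 83 of the 84 list calls. It ended that of thymocyte genes for the interaction (camera adjusted p from 0.025 to 0.057), which an estimated correlation also ended (0.079), and added ribosome biogenesis when fresh (0.042, lower) and when rested (0.028, higher). The replicate block common to all groups gave 1647, 1186, 7410, 7155, 7990, 7404 and 66 calls in the order of the comparisons, with r = 0.509 for fresh with rested. It changed no named gene and 3 lists. CD8, NK and gamma-delta markers in rested against fresh CD5lo cells went to an adjusted p of 0.054, and helper lineage (0.0496) and erythroid genes (0.049) in Treg against CD5hi cells were added. Only the compared groups gave 2183 calls for fresh and 495 for rested CD5hi against CD5lo, and rested replicates 3 and 4 alone 639 for the latter. DESeq2 called 130 interaction genes. Without a filter on low counts, the correlations were 0.166 for the CD5hi-to-CD5lo differences, 0.542 for resting in both CD5 groups and 0.389 for CD5hi with Treg. With the stricter filter they were 0.664, 0.902 and 0.483, where the genes entering the correlation differ. Resting changes correlated at 0.696 in male libraries, with 1 rested library per CD5 group, at 0.768 with rested replicates 1 and 2 and at 0.783 with 3 and 4. With an estimated correlation, 31 of the 84 list calls remained, and by fry 75. Without 1 library, calls ranged from 1218 to 1332 for fresh CD5hi against CD5lo, 834 to 1468 for rested, 6330 to 7318 and 6305 to 6850 for resting in CD5lo and CD5hi cells, 7207 to 7414 and 6579 to 6801 for Treg against CD5lo and CD5hi, and 36 to 90 for the interaction. The correlations ranged from 0.429 to 0.50, 0.801 to 0.837 and 0.397 to 0.474 in the order above, and the share of fresh calls repeated after resting from 41.3 to 54.8%. The cause of these shifts was not tested. With sex as a covariate 1672, 1220, 7324, 7052, 7537, 7066 and 71 genes were called, 6374 and 6116 of those for resting and 6745 and 6228 of those for Treg being calls of the fit without it. DESeq2 size factors moved the median of all genes by at most 0.03 on the log2 scale. Depth limits genes such as C1qa, Lrrc32, Penk and Klrg1, with 2 counts or fewer in a group.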

Other observations

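Several gene groups had no place in the comparisons above. Cytosolic ribosomal proteins were lower in Treg in 70 and 60 of 85 and higher in 3 and 3 against CD5lo and CD5hi cells (3 and 73 adjusted over the list alone, and 3 and 63 adjusted over the list alone). For ribosomal proteins the camera adjusted p was 3.8e-08 and 3.5e-07, and adjusted p = 0.60 and 0.64 with an estimated correlation. Ribosome biogenesis genes were lower in 22 and 21 of 30 and higher in 1 and 0 (1 and 22 adjusted over the list alone, and 0 and 24 adjusted over the list alone). For ribosome biogenesis the camera adjusted p was 8.6e-05 and 1.4e-04, and adjusted p = 0.30 and 0.31 with an estimated correlation. Chromatin modifiers fell in 19 and 19 and rose in 6 and 7 of 38 (6 and 20 adjusted over the list alone, and 7 and 19 adjusted over the list alone). For chromatin modifiers the camera adjusted p was 0.011 and 0.015, and adjusted p = 0.42 and 0.44 with an estimated correlation. Circadian clock genes, which include Bhlhe40, rose in 11 and 11 and fell in 1 and 1 of 17 in Treg (12 and 2 adjusted over the list alone, and 11 and 1 adjusted over the list alone). For clock genes the camera adjusted p was 0.0040 and 9.8e-04, and adjusted p = 0.039 and 0.020 with an estimated correlation. Adhesion and chemokine receptor genes rose in 14 and 14 and fell in 4 and 5 of 25 (14 and 4 adjusted over the list alone, and 15 and 5 adjusted over the list alone). For adhesion genes the camera adjusted p was 0.0034 and 0.0057, and adjusted p = 0.039 and 0.048 with an estimated correlation. Dendritic cell and MHC class II genes rose in 8 and 7 and fell in 1 and 1 of 12 (9 and 1 adjusted over the list alone, and 7 and 1 adjusted over the list alone; camera adjusted p = 0.21 and 0.11).

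On resting in CD5lo and CD5hi cells, helper lineage and Tfh regulators fell in 13 and 14 and rose in 6 and 6 of 25 (6 and 13 adjusted over the list alone, and 7 and 14 adjusted over the list alone). For helper lineage genes the camera adjusted p was 0.19 and 0.029, and adjusted p = 0.59 and 0.31 with an estimated correlation. Oxidative phosphorylation genes rose in 25 and 25 and fell in 6 and 4 of 79 (15 and 5 adjusted over the list alone, and 20 and 4 adjusted over the list alone). For oxidative phosphorylation the camera adjusted p was 0.079 and 0.043, and adjusted p = 0.85 and 0.84 with an estimated correlation. Clock genes rose in 9 and 9 and fell in 1 and 2 of 17 (9 and 1 adjusted over the list alone, and 9 and 2 adjusted over the list alone). For clock genes the camera adjusted p was 0.094 and 0.024, and adjusted p = 0.19 and 0.091 with an estimated correlation. Ribosomal proteins rose in 24 and fell in 4 of 85 in CD5lo cells (10 and 3 adjusted over the list alone), and the camera adjusted p was 0.042, and adjusted p = 0.85 with an estimated correlation. Glycolysis genes rose in 7 and 8 and fell in 6 and 7 of 19 (7 and 6 adjusted over the list alone, and 8 and 8 adjusted over the list alone; camera adjusted p = 0.58 and 0.65). Genes of the amino acid and ATF4 response rose in 6 and 8 and fell in 8 and 6 of 21 (6 and 8 adjusted over the list alone, and 8 and 6 adjusted over the list alone; camera adjusted p = 0.61 and 0.78). Glucocorticoid-responsive genes rose in 6 and 5 and fell in 4 and 4 of 16 (6 and 4 adjusted over the list alone, and 5 and 4 adjusted over the list alone; camera adjusted p = 0.43 and 0.56). Immediate early and heat shock genes rose in 6 and 4 and fell in 5 and 2 of 19 (7 and 5 adjusted over the list alone, and 4 and 2 adjusted over the list alone; camera adjusted p = 0.57 and 0.43). Their median changes were 0.23 and 0.20 and their means -0.23 and -0.11. The ATF4 list had a median of 0.01 and a mean of -0.15 in CD5lo cells, and the glucocorticoid list a median of 0.15 and a mean of -0.0024 in CD5hi cells.

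Between CD5hi and CD5lo cells and for the interaction, some lists passed camera at the preset correlation with few or no members called, and none of the calls in this group held with an estimated correlation. Of 85 ribosomal proteins, edgeR called 0 when fresh, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 and 0 by limma-voom, and 3 fell when rested (0 and 1 adjusted over the list alone). For ribosomal proteins the camera adjusted p was 0.022 and 1.8e-08, and adjusted p = 0.84 and 0.59 with an estimated correlation. ATF4 response genes rose in 4 and fell in 1 of 21 when rested (5 and 1 adjusted over the list alone), and the camera adjusted p was 0.018, and adjusted p = 0.22 with an estimated correlation. For the interaction, edgeR, DESeq2 and limma-voom called 0 interferon-stimulated genes (8 at an unadjusted p under 0.05), and the camera adjusted p was 2.1e-04, and adjusted p = 0.37 with an estimated correlation. Quiescence genes had 0 edgeR, 2 DESeq2 and 0 limma-voom calls there (7 unadjusted), and the camera adjusted p was 5.1e-05, and adjusted p = 0.13 with an estimated correlation. Of 13 thymocyte genes, the 3 tools called 0 for the interaction (5 unadjusted in edgeR; 2 and 0 adjusted over the list alone), and the camera adjusted p was 0.025, and adjusted p = 0.079 with an estimated correlation. The 3 tools also called 0 helper lineage genes (3 unadjusted), ribosome biogenesis genes (2), ribosomal proteins (0) and ATF4 response genes (3). Their camera adjusted p was 6.7e-04, 6.3e-05, 9.8e-04 and 0.0077 in that order, and adjusted p = 0.11, 0.30, 0.79 and 0.16 with an estimated correlation.

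The spread between replicates was larger in rested than in fresh cells. The common biological coefficient of variation was 7.72% in fresh CD5lo, 7.07% in fresh CD5hi, 13.5% in rested CD5lo, 14.4% in rested CD5hi and 9.90% in Treg libraries. Rested replicates 1 and 2 differed by only 6.04 (CD5lo) and 4.92 (CD5hi) times the sampling noise, below fresh pairs at 7.36 to 27.8. Rested pairs of 1 or 2 with 3 or 4 stood at 25.5 to 75.9, and 3 with 4 at 13.9 and 88.3. The larger rested spread thus lay between sets of replicates and does not show that resting makes cells more variable.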
